A study of Mus musculus with 46 samples.

How the data were processed

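Bulk RNA was sequenced from 46 mouse libraries. The submitters' processing notes name kallisto 0.46.1 and the mouse assembly GRCm38. The deposited table holds 46264 gene symbols and gives estimated counts (expected counts, a length-scaled form of TPM), per the labels and its name, and each library keeps its own total. The summing of transcripts to gene symbols, the scaling tool and any filter are not stated. Values were rounded to whole numbers. Normalised read counts (CPM, with TMM factors for the genes compared and from the totals alone for the tissue markers) are given as mean ± SD over the libraries of a group.

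Each group was taken from the tissue and condition fields and the title of its libraries. The treatment field differed from the condition field in 34 of the 46 libraries, and in 7 of the 34 blood, cell and skin libraries it held a time, so it was not used. Some neutrophil libraries carry series and animal numbers that stand for the opposite treatment in blood or monocytes. The labels do not say which libraries come from separate animals or cultures, so each p-value measures only the spread between these libraries.

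Within blood, neutrophils, monocytes and skin, libraries from mice given intravenous immunoglobulin (IVIG) were compared with those from mice given phosphate-buffered saline (PBS). The 3 times of the experiment labelled Ics were fitted together and compared in pairs. The difference between the IVIG effects of blood, neutrophils and monocytes was tested in a joint fit. Some titles share a series and animal number across these tissues, and the fit had no block for it. Every comparison used the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM scaling and the default expression filter (minimum count 10), and Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Genes past that limit are said to have risen or fallen. The standard error (SE) of a log2 change was its size divided by the square root of F. Adjusted p-values without another name come from edgeR.

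Before the data were examined, 37 gene lists were fixed, with 558 genes of which 555 are in the table, together with the comparisons and alternatives. Each list with at least 5 tested members was tested with camera of limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry. The rule for naming genes, fixed at the same time, took the 12 largest rises and 12 largest falls with a mean of at least 5 CPM in the higher group, up to 4 members of each list by smallest p, and 10 genes in every comparison. Those 10 were Fcgr1, Fcgr2b, Fcgr3, Fcgr4, Fcer1g, C5ar1, Il1b, Tnf, S100a8 and S100a9. Where fewer than 10 genes passed, the rule took the 10 with the smallest p. Other named genes were chosen after their values were seen, and the text says so. The 200 genes that rose most and the 200 that fell most at 3 h in the Ics experiment were tested as sets in the IVIG comparisons.

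Alternatives were DESeq2 1.42.0, limma voom with quality weights, other scaling, no expression filter, an adjusted p limit of 0.1, title series as a covariate or subset, blocks by replicate number, leaving out haemoglobin or receptor segment genes, and leaving out each library in turn. Alternatives without the libraries whose markers contradict their label were added after the data were seen. The procedure was tested on simulated data made from these libraries, with 200 genes changed. A pairwise check of 77 library pairs found 0 identical pairs. Gene positions were read from GENCODE vM21 on GRCm38, which held 86 of 87 symbols looked up.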

Results

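The series profiled gene expression in mice from a model of mucous membrane pemphigoid, a blistering disease with autoantibodies against laminin 332 of the epithelial basement membrane. IVIG is pooled immunoglobulin given into a vein. Blood and neutrophils had 5 libraries with IVIG and 5 with PBS each. Monocytes had 3 with IVIG and 5 with PBS, and skin had 3 of each. A separate experiment labelled Ics had 4 libraries at each of 0 h (titled unstimulated), 3 h and 6 h, and its labels neither expand Ics nor name the cells. Library totals were 27419349 to 43176793 estimated counts for blood, 19784909 to 37487558 for neutrophils, 18965434 to 39014292 for monocytes, 29202861 to 33276385 for skin and 24827887 to 29502869 for Ics. Between 6468 and 18702 genes had at least 5 counts in a library.

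In the Ics experiment, the first question was which genes differed 3 h after the unstimulated state. Among the genes taken by the naming rule, Havcr2, Tlr9, Cd83 and Nr4a3 rose most. Havcr2 (chromosome 11, 46454935 to 46481255), which codes the inhibitory receptor TIM-3, rose by 7.18 ± 0.24 on the log2 scale (SE, n = 4 and 4 libraries), from 0.136 ± 0.0544 to 20.4 ± 3.36 CPM (adjusted p = 1.22e-11 in edgeR). Tlr9 (chromosome 9, 106222598 to 106226883), a sensor of unmethylated DNA, rose by 6.71 ± 0.165, to 52.4 ± 7.32 CPM. Icam1 (chromosome 9, 21015985 to 21028817), a ligand of leukocyte integrins, rose by 6.15 ± 0.189, from 5.52 ± 0.943 to 391 ± 64.6 CPM. Cd83 rose by 6.52 ± 0.238, the acute phase gene Saa3 by 6.12 ± 0.316 and the nuclear receptor Nr4a3 by 6.30 ± 0.265. For each of these 6 genes, all 4 libraries at 3 h were above all 4 at 0 h.

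Of 25 tested cytokine and NF-kB target genes, 23 rose and 2 fell at 3 h, and adjusted over the list alone 23 rose and 2 fell (camera adjusted p = 1.51e-09, and adjusted p = 0.528 with an estimated correlation). Tnf rose by 4.26 ± 0.164, from 22.9 ± 4.05 to 438 ± 59.5 CPM. Il1rn, the natural antagonist of the interleukin 1 receptor, rose by 2.54 ± 0.0722, Nfkb1 by 1.80 ± 0.0725 and Il1b by 0.53 ± 0.0753. The members that fell, named after their values were seen, were the prostaglandin synthase gene Ptgs2 at -1.11 ± 0.131 and the cytokine gene Osm at -1.78 ± 0.0948. Of 15 genes of Fc gamma receptors and their signalling, 10 rose and 2 fell, with 10 and 2 adjusted over the list alone (camera adjusted p = 0.0107, and adjusted p = 0.469 with an estimated correlation). The activating receptor gene Fcgr3 rose by 0.95 ± 0.0488. The inhibitory receptor gene Fcgr2b (chromosome 1, 170958617 to 170976547) rose by 1.03 ± 0.0927, from 55.5 ± 4.72 to 113 ± 12.0 CPM. Fcgr4 did not pass, at -0.02 ± 0.0585 (adjusted p = 0.765). Card9, an adaptor of antifungal and Fc receptor signalling, fell by 1.42 on the log2 scale. Of 20 adhesion and migration genes, 13 rose and 4 fell, with 13 and 4 adjusted over the list alone (camera adjusted p = 0.0364, and adjusted p = 0.577 with an estimated correlation). The integrin gene Itgal rose by 1.60 ± 0.0638 and the formyl peptide receptor gene Fpr1 by 1.91 ± 0.0771.

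Interferon-stimulated genes fell at 3 h: of 23 tested, 20 fell and 1 rose, with 20 and 1 adjusted over the list alone (camera adjusted p = 1.01e-08, and adjusted p = 0.451 with an estimated correlation). Oas3 (chromosome 5, 120753098 to 120777661), a sensor of double-stranded RNA, fell by 2.17 on the log2 scale, from 189 ± 20.0 to 41.9 ± 2.64 CPM. Cmpk2 fell by 2.49 and Ifit1 by 2.19. The member that rose was the chemokine gene Cxcl10, at 4.13 ± 0.214, named after its value was seen.

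Transcripts of red cells, platelets, neutrophil granules and the cell cycle also fell at 3 h. The erythroid list had 18 of 19 members fall and 0 rise, with 18 and 0 adjusted over the list alone (camera adjusted p = 2.49e-05, and adjusted p = 0.666 with an estimated correlation). Slc4a1 (chromosome 11, 102348824 to 102366203), the anion exchanger of the red cell membrane, went from 30.1 ± 8.68 to 2.32 ± 1.14 CPM, a log2 change of -3.69 ± 0.364. The platelet list had 9 of 12 members fall and 0 rise, with 9 and 0 adjusted over the list alone (camera adjusted p = 0.00264, and adjusted p = 0.451 with an estimated correlation). The chemokine gene Ppbp (chromosome 5, 90768518 to 90770063) went from 13.5 ± 4.09 to 0.455 ± 0.909 CPM and had counts in only 1 library at 3 h. Itgb3, an integrin subunit, went from 105 ± 2.90 to 24.5 ± 1.69 CPM. Of 7 primary granule genes 6 fell and 0 rose, with 6 and 0 adjusted over the list alone (camera adjusted p = 0.0442, and adjusted p = 0.79 with an estimated correlation). Mpo went from 89.6 ± 31.3 to 33.2 ± 14.7 CPM and Elane from 60.6 ± 20.3 to 19.2 ± 7.92 CPM. Of 16 secondary and tertiary granule genes 12 fell and 1 rose, with 12 and 1 adjusted over the list alone (camera adjusted p = 0.00168, and adjusted p = 0.577 with an estimated correlation). Ly6g was at -0.91 ± 0.0676, and the riser, named after its value was seen, was Olfm4 at 0.60 ± 0.0865. Of 20 proliferation genes 13 fell and 1 rose, with 13 and 1 adjusted over the list alone (camera adjusted p = 0.00457, and adjusted p = 0.79 with an estimated correlation). The calprotectin gene S100a8, abundant in neutrophils, did not pass, at -0.04 ± 0.0885 (adjusted p = 0.71). S100a8 and S100a9 together held 28700 to 49400 CPM in the 12 Ics libraries.

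In all, 4034 genes rose and 4129 fell among 14996 tested at 3 h against 0 h, and 1346 and 1431 of these changed at least 2-fold. The 3 h and 6 h groups have no unstimulated libraries of the same time, so the stimulus and the time in culture are not separated.

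**Figure D1:**
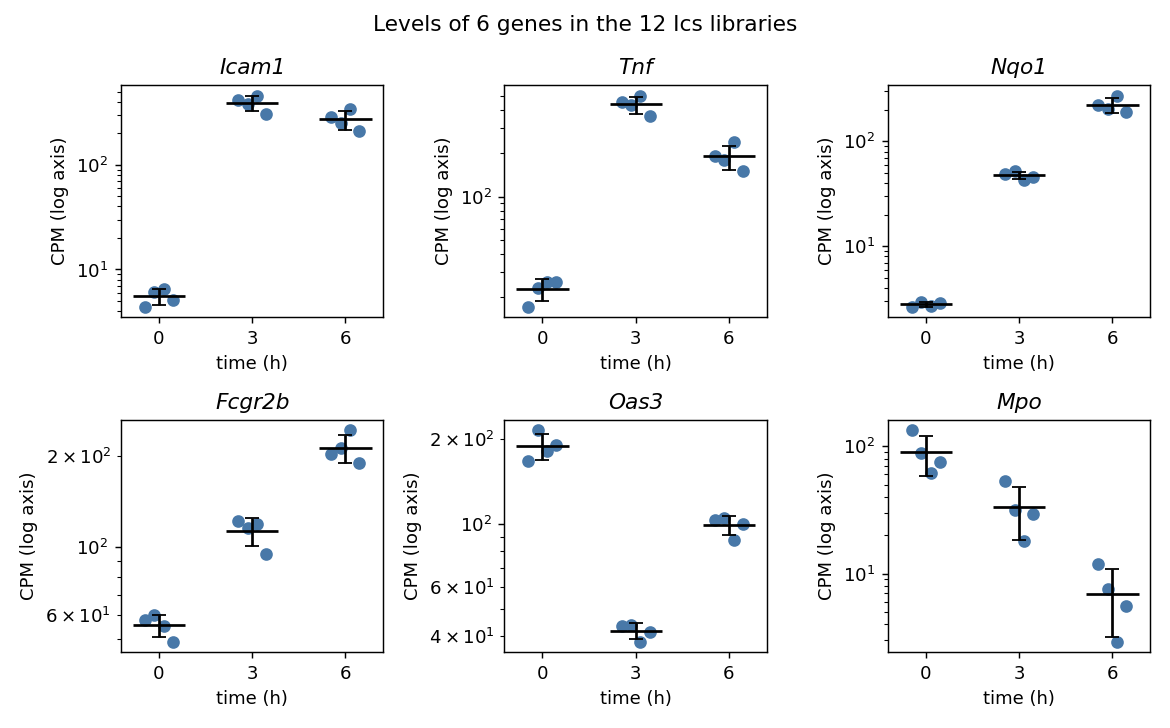
Levels of Icam1, Tnf, Nqo1, Fcgr2b, Oas3 and Mpo in CPM on log axes against time in hours, for the 12 Ics libraries (points), with the mean of the 4 libraries per time (line) and its SD (bar). Icam1 went from 5.52 CPM at 0 h to 391 at 3 h, Oas3 from 189 to 41.9, and Nqo1 reached 222 at 6 h.

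At 6 h against 0 h, Nqo1, Srxn1 and Prdx1, genes of the oxidant defence, were among the 12 largest rises taken by the naming rule. Nqo1 (chromosome 8, 107388225 to 107403206), a quinone reductase, rose by 6.31 ± 0.131 on the log2 scale (SE, n = 4 and 4 libraries), from 2.79 ± 0.15 to 222 ± 37.0 CPM (adjusted p = 7.01e-13 in edgeR). Srxn1, which repairs oxidised peroxiredoxins, rose by 5.94 ± 0.209, and the peroxiredoxin gene Prdx1 by 6.16 ± 0.226, from 6.96 ± 1.37 to 498 ± 151 CPM. Havcr2 rose by 7.51 ± 0.239 and Tlr9 by 6.20 ± 0.165. For each of these 5 genes, all 4 libraries at 6 h were above all 4 at 0 h.

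Of the 25 cytokine and NF-kB target genes, 17 rose and 4 fell at 6 h, and adjusted over the list alone 19 rose and 4 fell (camera adjusted p = 0.000561, and adjusted p = 0.633 with an estimated correlation). Tnf was at 3.06 ± 0.157 and Il1b at -0.34 ± 0.0752 (adjusted p = 0.00116). The chemokine gene Ccl3 rose by 3.46 ± 0.189. Of the 15 Fc gamma receptor and signalling genes, 8 rose and 1 fell, with 8 and 1 adjusted over the list alone (camera adjusted p = 0.0259, and adjusted p = 0.595 with an estimated correlation). Fcgr2b rose by 1.93 ± 0.0941, to 211 ± 22.7 CPM, and Fcgr3 by 0.98 ± 0.0488. Fcgr4 was at 0.04 ± 0.0584 (adjusted p = 0.593), and Card9 was the member that fell. Of 23 interferon-stimulated genes 18 fell and 1 rose, with 18 and 1 adjusted over the list alone (camera adjusted p = 2.83e-05, and adjusted p = 0.595 with an estimated correlation). Zbp1 was at -2.29 ± 0.164 and Cmpk2 at -2.34 ± 0.112. The member that rose was again Cxcl10, at 3.20 ± 0.213.

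The erythroid list had 18 of 19 members fall and 1 rise at 6 h, with 18 and 1 adjusted over the list alone (camera adjusted p = 2.83e-05, and adjusted p = 0.614 with an estimated correlation). The riser was the transferrin receptor gene Tfrc, at 1.15 ± 0.149, which proliferating cells of many types also express and which was named after its value was seen. Slc4a1 reached 0.667 ± 0.424 CPM. The platelet list had 9 of 12 members fall and 1 rise, with 9 and 2 adjusted over the list alone (camera adjusted p = 0.00431, and adjusted p = 0.472 with an estimated correlation). Of 7 primary granule genes 6 fell and 0 rose, with 7 and 0 adjusted over the list alone (camera adjusted p = 0.00362, and adjusted p = 0.614 with an estimated correlation), and Mpo reached 6.97 ± 3.8 CPM. Of 16 secondary and tertiary granule genes 15 fell and 1 rose, with 15 and 1 adjusted over the list alone (camera adjusted p = 1.16e-07, and adjusted p = 0.472 with an estimated correlation). Ltf, which codes lactoferrin, was at -1.13 ± 0.057 and Cd177 at -1.12 ± 0.0514. Of 20 proliferation genes 16 fell and 0 rose, with 17 and 0 adjusted over the list alone (camera adjusted p = 0.000289, and adjusted p = 0.633 with an estimated correlation). Mki67 was at -0.81 ± 0.0932. In all, 4439 genes rose and 4560 fell among 14996 tested, and 1388 and 2006 changed at least 2-fold.

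Between 3 h and 6 h, 18 of the 25 cytokine and NF-kB target genes fell and 3 rose, with 18 and 4 adjusted over the list alone (camera adjusted p = 2.42e-06, and adjusted p = 0.626 with an estimated correlation). Il1rn was at -1.28 ± 0.0692 (SE, n = 4 and 4 libraries), Tnf at -1.20 ± 0.143 and Il1a at -2.27 ± 0.23. Nr4a3 was at -3.93 ± 0.222, from 149 ± 36.5 to 9.78 ± 2.03 CPM (adjusted p = 9.37e-09 in edgeR). Of 23 interferon-stimulated genes 12 rose and 3 fell, with 13 and 3 adjusted over the list alone (camera adjusted p = 0.0206, and adjusted p = 0.626 with an estimated correlation). Oas3 rose by 1.24 ± 0.0813, to 99.1 ± 7.67 CPM, and Rsad2 by 1.36 ± 0.0949.

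Of 18 hypoxia and glycolysis genes 10 rose and 4 fell between 3 h and 6 h, with 10 and 4 adjusted over the list alone (camera adjusted p = 0.0374, and adjusted p = 0.626 with an estimated correlation). The phosphofructokinase gene Pfkl rose by 2.25 ± 0.0897, the aldolase gene Aldoa by 1.01 ± 0.0747 and Ankrd37 by 3.38 ± 0.349. Of 20 adhesion and migration genes 14 fell and 2 rose, with 14 and 5 adjusted over the list alone (camera adjusted p = 0.0206, and adjusted p = 0.626 with an estimated correlation). Of 16 secondary and tertiary granule genes 10 fell and 0 rose, with 10 and 0 adjusted over the list alone (camera adjusted p = 1.94e-05, and adjusted p = 0.626 with an estimated correlation). Ngp was at -1.07 ± 0.0634. Of 7 primary granule genes 6 fell and 0 rose, with 6 and 0 adjusted over the list alone (camera adjusted p = 0.0304, and adjusted p = 0.626 with an estimated correlation), and Mpo was at -2.24 ± 0.385. In all, 3067 genes rose and 3050 fell among 14996 tested, and 524 and 806 changed at least 2-fold.

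**Figure D2:**
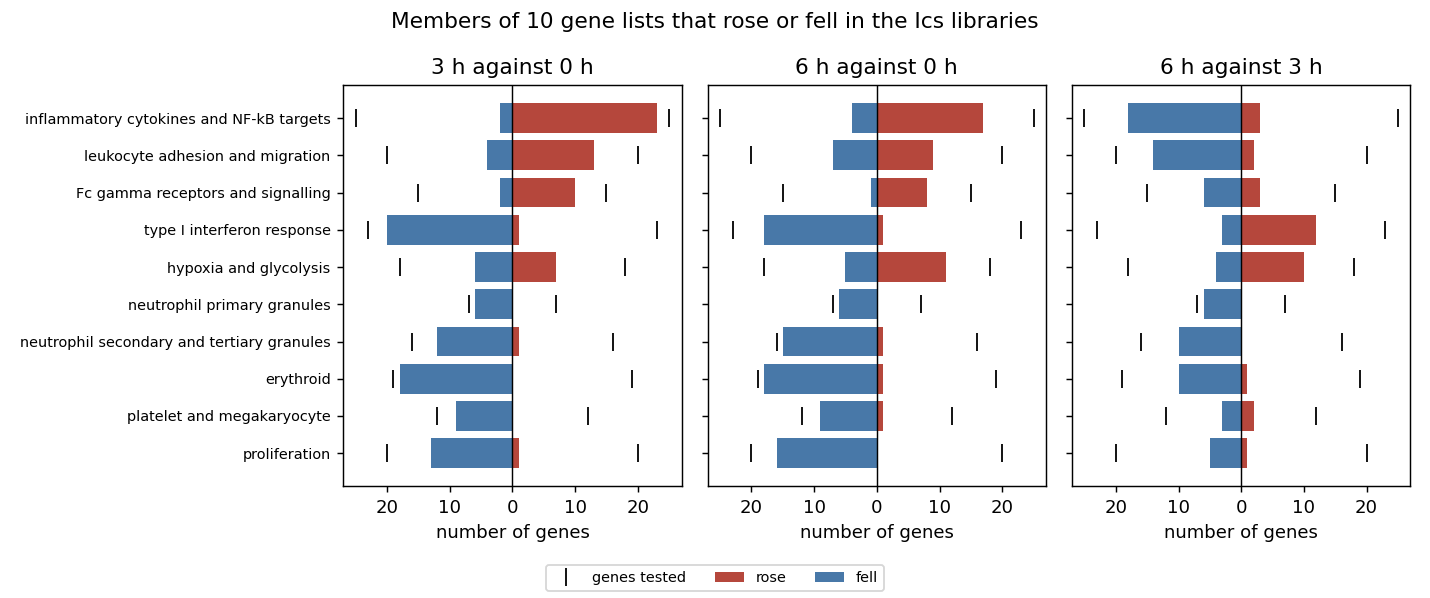
Number of members of 10 gene lists that rose (red, right) or fell (blue, left) in each Ics comparison by edgeR, with ticks at the number of genes tested on either side of 0. At 3 h, 23 of 25 cytokine and NF-kB target genes rose and 20 of 23 interferon-stimulated genes fell.

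Before the IVIG comparisons, the tissue markers of the 34 blood, cell and skin libraries were set against their labels. Haemoglobin transcripts held 89.2 to 98.3% of the counts in 10 libraries and at most 0.577% in the others. Another 10 libraries held 33700 to 71200 CPM of S100a8 and S100a9 together and 401 to 823 CPM of the neutrophil gene Ly6g. Another 6 held 310 to 1570 CPM of the basal keratin genes Krt5 and Krt14 together and 3900 to 12100 CPM of the collagen gene Col1a1. The last 8 had none of these marks, and held 1710 to 17100 CPM of the lysozyme gene Lyz2. Lyz2 does not set them apart, with 8580 to 15800 CPM in the neutrophil class and 3460 to 12300 in the skin class. Csf1r, a gene of monocytes and macrophages, ran from 25.5 to 864 CPM in the 8, against 155 to 283 in the neutrophil class. This class therefore rests on the absence of the other marks. Classes were drawn at 10% haemoglobin, 100 CPM of both keratins and 10000 CPM of S100a8 and S100a9, limits chosen after the values were seen.

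By these markers, with the last class counted as monocyte, 25 of the 34 libraries belonged to the tissue of their label and 9 to another. Of 10 libraries labelled blood, 1 had neutrophil markers, 1 was in the class of most monocyte libraries and 2 had skin markers. Of 10 labelled neutrophil, 2 had blood markers. Of 8 labelled monocyte, 1 had neutrophil markers, and of 6 labelled skin, 2 had blood markers. The deposited names were kept in every comparison, and no sample was given another label. The IVIG comparisons below describe the libraries as labelled. A match of tissue markers does not vouch for the treatment label. Under another sort order of the names, examined further below, 29 of the 34 names would move and 22 of these would change treatment. The direction of each IVIG value below, in single genes, lists and differences between tissues, therefore holds only for the names as deposited.

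**Figure D3:**
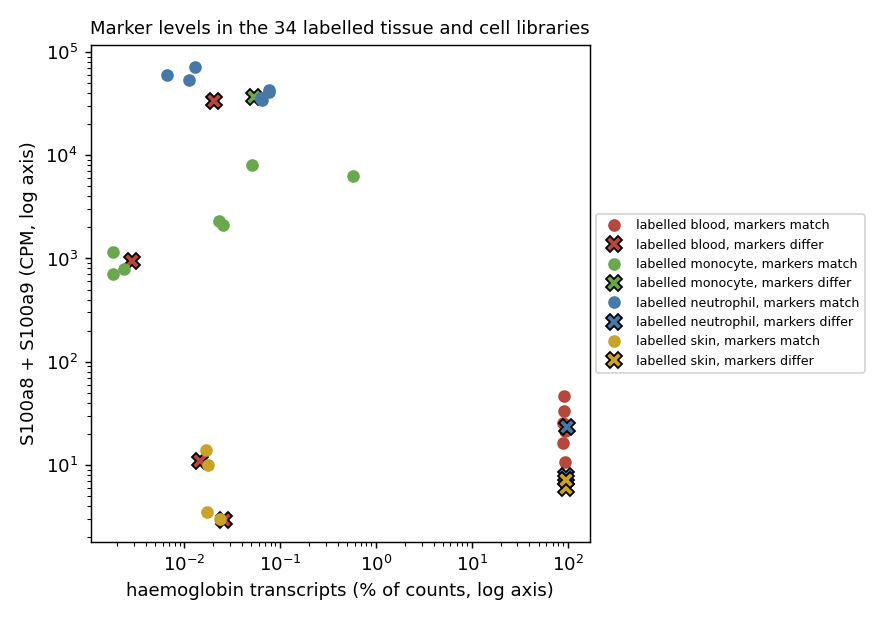
Haemoglobin transcripts (% of counts) against S100a8 plus S100a9 (CPM), both on log axes, for the 34 libraries outside the Ics experiment, coloured by labelled tissue, with crosses for the 9 libraries whose markers belong to another tissue. Libraries of the blood class lie at 89.2 to 98.3% haemoglobin, and 2 crosses labelled neutrophil and 2 labelled skin lie among them.

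In the libraries labelled blood, the question was what IVIG changed in circulating cells, and 0 genes passed in edgeR. S100a9 was at -4.46 ± 2.02 on the log2 scale (SE, n = 5 and 5 libraries, adjusted p = 0.9999), with 46.98 ± 44.3 CPM under IVIG and 1031 ± 2210 under PBS. The gelatinase gene Mmp9 was at -5.06 ± 1.65 (adjusted p = 0.9999). Fcgr2b, a receptor proposed in the field to take part in IVIG action, was at 0.24 ± 0.421 (adjusted p = 0.9999), and between 0.01 without the library labelled Blood_IVIG replicate 3 and 0.42 without Blood_PBS replicate 2. Without the library labelled Blood_PBS replicate 1, which had neutrophil markers, S100a9 was at 0.20 ± 1.25, and among the 6 libraries with blood markers S100a9 was at -0.44 ± 0.484 and Mmp9 at -0.72 ± 0.496. The interferon-stimulated genes had a median of 0.786 (camera adjusted p = 3.19e-09, and adjusted p = 0.638 with an estimated correlation), or 0.167 (camera adjusted p = 0.121) without the library labelled Blood_IVIG replicate 3, which had skin markers, and -0.0844 (camera adjusted p = 0.642) among the 6 with blood markers. In that library Ifit3 had 30.9 CPM, against 2.67 to 5.69 CPM in the other 9. Beside them, mitochondrially coded transcripts had a median of 0.429 (camera adjusted p = 2.18e-09, and adjusted p = 0.997 with an estimated correlation), and 0.853 among the 6 (camera adjusted p = 1.09e-06, and adjusted p = 0.336 with an estimated correlation). The T cell and NK cell list had a median of 0.0867 (camera adjusted p = 0.00961, and adjusted p = 0.997 with an estimated correlation), and 0.0692 among the 6 (camera adjusted p = 0.999). The mature neutrophil list had a median of -2.16 (camera adjusted p = 0.00242, and adjusted p = 0.997 with an estimated correlation), and 0.126 (camera adjusted p = 0.281) without Blood_PBS replicate 1. The secondary and tertiary granule list had a median of -3.42 (camera adjusted p = 0.00215, and adjusted p = 0.997 with an estimated correlation), and 1.24 (camera adjusted p = 0.162) without that library. Among the 6 they were at -0.282 (camera adjusted p = 0.00469, and adjusted p = 0.48 with an estimated correlation) and -0.683 (camera adjusted p = 5.62e-06, and adjusted p = 0.179 with an estimated correlation). With all 10 libraries, 0 members of these 5 lists passed, over all genes or adjusted over the list alone. The list tests with fewer libraries, here and below, were added after the data were seen.

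By edgeR 0 of 11339 genes passed in the libraries labelled blood, with 81 at an unadjusted p under 0.05 where 567 were expected by chance. DESeq2 called 1 gene (Gm15501) and limma voom 1 gene (Gm20716). In the 6 libraries labelled blood with blood markers (3 with IVIG and 3 with PBS by label), an alternative added after the data were seen, 5 genes passed: Gm15501, Gm20716, Gm49393, Gm9385 and Rab11b-ps2. All 5 are predicted genes or pseudogenes by their names, and they are named here after their values were seen. Under the sort order described below, Blood_IVIG replicate 1, among these 6, would carry PBS instead, while the others keep their names. The values among the 6, here and above, hold only for the names as deposited.

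In the libraries labelled neutrophil, Fcgr2b was at 0.09 ± 0.302 (SE, n = 5 and 5 libraries, adjusted p = 0.9999), with 34.5 ± 6.74 CPM under IVIG and 32.5 ± 10.6 under PBS, and at -0.10 ± 0.217 without the library labelled Neutrophil_PBS replicate 1, which had blood markers. The gene with the smallest p, Cntd1, was at -6.31 ± 2.01 (adjusted p = 0.9999), and at -0.655 ± 0.468 among the 8 libraries with neutrophil markers. The cytosolic ribosomal protein list had the smallest camera p, with a median of -0.222 (camera adjusted p = 0.000117, and adjusted p = 0.952 with an estimated correlation), and -0.0836 (camera adjusted p = 0.533) without Neutrophil_PBS replicate 1. The list of MHC class II presentation had a median of -1.68 (camera adjusted p = 0.00204, and adjusted p = 0.952 with an estimated correlation), or 0.548 (camera adjusted p = 0.252) without that library and -0.591 among the 8 libraries with neutrophil markers (camera adjusted p = 0.000509, and adjusted p = 0.981 with an estimated correlation). H2-Ab1 had 461 CPM in that library and 98.1 in Neutrophil_IVIG replicate 5, which also had blood markers, against 5.66 to 32.4 CPM in the 8. The TMM factors behind these CPM were 0.0712 in Neutrophil_PBS replicate 1 and 0.0244 in Neutrophil_IVIG replicate 5. They were 1.91 to 2.36 in the 8, so this contrast depends on the scaling. The MHC class II list stood beside a median of -1.14 for 12 tested B cell and plasma cell genes (camera adjusted p = 0.0955). The erythroid list had a median of 0.511 while its test pointed down (camera adjusted p = 0.0248, and adjusted p = 0.952 with an estimated correlation). Haemoglobin, part of that list, held 96.3% of the counts in Neutrophil_PBS replicate 1 and 98.3% in Neutrophil_IVIG replicate 5. It held at most 0.0775% in the 8 libraries with neutrophil markers. Mitochondrially coded transcripts had a median of 0.417 (camera adjusted p = 0.0155, and adjusted p = 0.952 with an estimated correlation), and -0.148 among the 8 (camera adjusted p = 0.888). The skeletal muscle list had a median of -0.396 (camera adjusted p = 0.00204, and adjusted p = 0.952 with an estimated correlation), and -0.347 among the 8 (camera adjusted p = 0.000725, and adjusted p = 0.981 with an estimated correlation). The mature neutrophil list was called up at a median of 0.00929 (camera adjusted p = 0.0305, and adjusted p = 0.952 with an estimated correlation), and was at -0.0176 among the 8 (camera adjusted p = 0.822). With all 10 libraries, 0 members of these 7 lists passed, over all genes or adjusted over the list alone. By edgeR 0 of 14033 genes passed, with 73 at an unadjusted p under 0.05 where 702 were expected. DESeq2 and limma voom called 0, with 88 and 1980 at an unadjusted p under 0.05. Among the 8 libraries with neutrophil markers edgeR called 0, with 134 at an unadjusted p under 0.05. Under the sort order of the names described below, 9 of the 10 libraries with neutrophil markers would change treatment, these 8 among them. The signs of the values among the 8 hold only for the names as deposited.

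In the libraries labelled monocyte, Psmb10, a subunit of the immunoproteasome, was at 1.20 ± 0.312 (SE, n = 3 and 5 libraries, adjusted p = 0.9999), with 174 ± 71.4 CPM under IVIG and 75.6 ± 15.1 under PBS. Wdr89 was at 2.69 ± 0.603 and Fcgr2b at -0.25 ± 0.357 (adjusted p = 0.9999 for both). Fcgr2b was at -0.08 without the library labelled Monocyte_IVIG replicate 2 and at -0.52 without Monocyte_IVIG replicate 3. The secondary and tertiary granule list had a median of -1.68 (camera adjusted p = 0.00981, and adjusted p = 0.844 with an estimated correlation), and -0.426 (camera adjusted p = 0.82) without the library labelled Monocyte_PBS replicate 1, which had neutrophil markers. Also called were skeletal muscle at a median of 1.43 (camera adjusted p = 3.64e-07) and cytosolic ribosomal proteins at 0.149 (camera adjusted p = 0.000302). So were oxidative phosphorylation at 0.112 (camera adjusted p = 0.0118), mature neutrophil at -1.8 (camera adjusted p = 0.0162) and leukotriene genes at -1.27 (camera adjusted p = 0.0332). Each had an adjusted p of 0.844 with an estimated correlation. No member of these 6 lists passed, over all genes or adjusted over the list alone. By edgeR 0 of 14415 genes passed, with 286 at an unadjusted p under 0.05 where 721 were expected. DESeq2 called 3 (Gm12918, Ighg2c and Tinagl1, named after their values were seen) and limma voom 0, with 849 at an unadjusted p under 0.05. Among the 7 libraries in the class of their label edgeR called 0, with 306 at an unadjusted p under 0.05. Under the sort order of the names described below, every library labelled Monocyte_IVIG would carry PBS instead. The signs in the monocyte comparison hold only for the names as deposited.

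In the libraries labelled skin, where the question was what IVIG changed in the affected tissue, hair follicle genes had the highest median, 2.86 on the log2 scale (camera adjusted p = 9.95e-08, and adjusted p = 0.29 with an estimated correlation). Of 9 tested members 0 passed over all genes and 4 rose adjusted over the list alone. Other tissue lists also differed. Epidermal differentiation genes had a median of 0.444 (camera adjusted p = 0.0343, and adjusted p = 0.945 with an estimated correlation). Skeletal muscle genes were at -2.63 (camera adjusted p = 0.0576). S100a3, a calcium-binding protein of the hair shaft, was at 5.55 ± 1.33 (SE, n = 3 and 3 libraries), with 5.78 ± 4.67 CPM under IVIG and 0.091 ± 0.115 under PBS. It did not pass in edgeR (adjusted p = 1) and passed in DESeq2 (adjusted p = 0.0262). Interferon-stimulated genes had a median of -1.66 (camera adjusted p = 4.19e-24, and adjusted p = 0.197 with an estimated correlation), with Oasl1 at -2.35 ± 0.651. Fc gamma receptor and signalling genes had a median of -0.762 (camera adjusted p = 5.89e-09, and adjusted p = 0.155 with an estimated correlation), with Fcgr2b at -0.69 ± 0.507, or -0.37 ± 0.445 without the library labelled Skin_IVIG replicate 3, which had blood markers. Beside it, the median was -0.596 for adhesion and migration genes (camera adjusted p = 1.46e-05, and adjusted p = 0.297 with an estimated correlation) and -0.465 for mature neutrophil genes (camera adjusted p = 0.00126, and adjusted p = 0.38 with an estimated correlation). Without the library labelled Skin_PBS replicate 1, which had blood markers, these medians were 0.18 (test still down, camera adjusted p = 0.00365, and adjusted p = 0.682 with an estimated correlation) and 0.173 (camera adjusted p = 0.203). The monocyte and macrophage list was not called, with a median of -0.267 (camera adjusted p = 0.0643) and F13a1 at 1.14 ± 0.723, nor was the T cell and NK cell list, with a median of 0.205 (camera adjusted p = 0.858) and Trac at 0.91 ± 1.10. Proliferation genes had a median of 1.26 (camera adjusted p = 2.7e-16, and adjusted p = 0.197 with an estimated correlation). Apart from the hair follicle list, no member of these lists passed, over all genes or adjusted over the list alone. The hair follicle, interferon, Fc gamma and proliferation medians above include a library with blood markers in each arm. Camera with the preset correlation called 14 lists with all libraries. Of these, 10 stayed called without Skin_PBS replicate 1, 12 without Skin_IVIG replicate 3 and 12 among the 4 libraries with skin markers, and 0 with an estimated correlation.

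By edgeR 0 of 16171 genes passed in the libraries labelled skin, with 157 at an unadjusted p under 0.05 where 809 were expected. DESeq2 called 1 (S100a3) and limma voom 0, with 1230 at an unadjusted p under 0.05. In the 4 libraries labelled skin with skin markers (2 with IVIG and 2 with PBS by label), an alternative added after the data were seen, 4 hair follicle genes rose: Krt25, Krt28, Krt71 and Tchh. Under both the sort order and the move by 1 place described below, each of these 4 libraries would carry the opposite treatment. The rise would then be a fall, so its direction holds only for the names as deposited. The same holds for the direction of the interferon, Fc gamma, adhesion, proliferation and other list medians in the libraries labelled skin.

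Camera with the preset correlation called 5 of 31 lists in the libraries labelled blood, 6 of 34 for neutrophil, 6 of 33 for monocyte and 14 of 36 for skin. With an estimated correlation, and by fry, it was 0 in each of the 4. In the simulated test, 0 of 100 genes changed 4-fold were recovered in the blood, monocyte and skin designs and 24 of 100 in the neutrophil design, against 99 or 100 of 100 in the Ics designs. A count of 0 in the blood, monocyte and skin comparisons therefore sets no limit on changes of that size.

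The difference between the IVIG effects of 2 tissues was tested over 17135 genes. The interferon-stimulated genes had a median difference of -0.783 for neutrophil against blood (camera adjusted p = 8.17e-16, and adjusted p = 0.0439 with an estimated correlation), and fry gave an adjusted p of 0.99. It was -0.24 without the library labelled Blood_IVIG replicate 3 (camera adjusted p = 0.00446, and adjusted p = 0.655 with an estimated correlation), and 0.207 (camera adjusted p = 0.777) with only libraries whose markers match their label. Of 7 leukotriene genes the median difference was 0.916 in the same comparison (camera adjusted p = 0.0377, and adjusted p = 0.559 with an estimated correlation), and -0.307 (camera adjusted p = 0.721) without Blood_PBS replicate 1. The skeletal muscle list had a median difference of 4.39 for monocyte against blood (camera adjusted p = 0.00048, and adjusted p = 0.996 with an estimated correlation). In the libraries labelled blood under PBS, its members Tnnt3 at 55.98 ± 122 CPM and Eno3 at 37.79 ± 70.9 had an SD above the mean. The value can thus rest on few libraries, and the list was not retested with fewer libraries in this comparison. By edgeR 0 genes passed for neutrophil against blood, monocyte against blood and neutrophil against monocyte, with 186, 677 and 776 at an unadjusted p under 0.05 where 857 were expected. DESeq2 called 10, 29 and 33 genes, and limma voom 1, 0 and 0. Libraries of another tissue class enter each of these 3 tests. Libraries that share a title series and animal number across tissues were treated as independent in them.

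The Ics response genes were then examined in the IVIG comparisons. The 200 genes that rose most at 3 h, of which 115 were tested in the libraries labelled blood, had a median of 0.208 there (camera adjusted p = 6.84e-05, and adjusted p = 0.702 with an estimated correlation). In the libraries labelled skin, 181 of them were tested, with a median of -0.21 (camera adjusted p = 0.000381, and adjusted p = 0.702 with an estimated correlation). The other 6 of the 8 set tests did not pass. The genes that fell had a median of 0.231 in the libraries labelled blood, while their test pointed down (camera adjusted p = 0.0691).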

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

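The tests of mixed material, of the order of the names, of a minor cell population and of time in culture were chosen after the result was seen, while the tests of other splits of the libraries were planned.

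The first pattern is the 9 of 34 libraries whose markers belong to another tissue than their label. Mixed or carried-over RNA is argued against, since the blood-labelled libraries among them held at most 0.0265% haemoglobin, against at least 89.2% in the blood class. The skin-labelled ones held 0 CPM of Krt5 and Krt14, against at least 309.9 in the skin class. A candidate explanation is that the column names were written in another sort order than the columns: under it 34 of 34 classes matched, and 0 of 33 libraries went against the sex genes (Xist or Y-linked) of their title series, against 10 by label. Names moved by 1 place among the 34, with the Ics names kept in place, also matched 34 of 34 classes. This left 2 libraries against their series, where the sort order left 0. The sex genes thus go with the sort order by 2 libraries, too few to exclude this move by 1 place. A move of all 46 names by 1 place would put blood names on Ics columns. The Ics libraries held at most 0.0235% haemoglobin, which argues against a move of the whole table. The other 32 moves matched at most 25. The Ics names and 5 blood names keep their place in the sort orders, 22 other names would change treatment, and which names are right is not stated in the labels.

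The libraries that stood apart from their group in these markers were as follows, each far from the nearest of the others relative to the range of its group. Haemoglobin was 98.3% in the library labelled Neutrophil_IVIG replicate 5 and 96.3% in Neutrophil_PBS replicate 1. S100a8 and S100a9 together were 939 CPM in Blood_IVIG replicate 2 (others 10.7 to 33.2), 33700 in Blood_PBS replicate 1 (others 2.95 to 46.4) and 37000 in Monocyte_PBS replicate 1 (others 795 to 8070). Krt5 and Krt14 together were 331 CPM in Blood_IVIG replicate 3, 940 in Blood_PBS replicate 2 and 0.435 in Neutrophil_PBS replicate 3. The library total was 39014292 counts in Monocyte_PBS replicate 1 (others 25170607 to 26068328) and 25372706 in Ics_3h replicate 3 (others 27876085 to 28365257).

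The second pattern is the fall of red cell and primary granule transcripts in the Ics experiment. If a minor population of cells differed in share between libraries, its genes would move together within a time. The mean correlation of their deviations from the group means was 0.392, above the 95th percentile of 0.0458 and the highest value of 0.118 in 1000 random sets. It was 0.496 for the erythroid list and 0.815 for the primary granule list. For the secondary and tertiary granule list, which also fell, it was 0.326, against a 95th percentile of 0.306, with 30 of 1000 random sets as high. Genes of the same cell type can move together for other reasons, and the deviations are those within a time. The test therefore does not decide on a loss of such cells between times, which stays a hypothesis. Time in culture cannot be told apart from the stimulus, since 0 libraries were kept unstimulated for 3 h or 6 h.

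Single Ics libraries stood apart from the other 3 of their time in 10 of 243 groups of gene values, where chance gives about 1 in 20 groups, or 12.2. At 0 h these were Cd14 at 102 CPM in replicate 3 (others 81.8 to 84.9) and Tfrc at 20.6 in replicate 2 (others 32.1 to 33.8). At 3 h they were Ankrd37 at 0.475 CPM in replicate 3, Blvrb at 17.2 in replicate 2 and Ppbp at 1.82 in replicate 1, where the other libraries had 0 for Ppbp. At 6 h, replicate 3 had Mki67 at 167 CPM, Olfm4 at 352 and Osm at 107, and replicate 1 had Pf4 at 0.0685 and Saa3 at 10.8. The change from 0 h differed between 3 h and 6 h for 6117 genes, by the test of the difference itself.

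Other splits of the same libraries were counted for each comparison. For Ics, 1 of 35 splits, the real one, gave as many genes in each of the 3 comparisons. The counts were 8163 against at most 1, 8999 against at most 0 and 6117 against at most 2 in other splits. This is the smallest share that 35 splits can give. It lies under 0.05 and argues against chance without excluding it. For the libraries labelled blood, neutrophil and monocyte the real count was 0, so that 100 of 100, 100 of 100 and 56 of 56 splits gave at least as many by construction, and these counts say nothing on chance. The highest split of the blood libraries gave 1032, with 5 blood-class libraries on its one side and all 4 of other classes on the other, where both libraries outside title series 3 stood too. That of the neutrophil libraries gave 347, with both blood-class libraries and all 3 libraries outside title series 3 on the same side, and that of the monocyte libraries gave 1. The blood and neutrophil splits point to a structure of the samples, and whether it follows tissue class or title series was not tested. Skin has only 10 splits, too few for a share under 0.05, with 0 in the real split and 0 in the highest other.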

How the results depend on the processing

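Fits without the libraries whose markers contradict their label or with only the blood names that keep their place in both sort orders, the leave-out fits of the differences between tissues, and the list tests with fewer libraries were chosen after the result was seen. The numbers of genes called in the Ics comparisons stayed within 1.5 times under each alternative run: 7690 to 8223 at 3 h, 8511 to 9220 at 6 h and 5526 to 6136 between them without each library in turn, and 8045, 8867 and 6104 by DESeq2. With the replicate number as a block they were 8297, 9151 and 6354. Residual correlations of the 12 same-number pairs were 0.0481 to 0.184, and those of the other 36 pairs -0.0978 to 0.0169, so that every library correlated best with its own number, a hint from the data. Only 8 of the 12 were above the 0.1 set for each of them, and the labels do not say what the number marks, so the libraries were not treated as paired.

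Counts that started from 0 rose in some settings, and the cause was not tested. DESeq2 gave 1 gene in the libraries labelled blood, 3 in monocyte and 1 in skin, and 10, 29 and 33 for the differences of neutrophil against blood, monocyte against blood and neutrophil against monocyte. Limma voom gave 1 in blood and 1 (Vdac3) for neutrophil against blood. Only libraries with the markers of their label gave 5 in blood, 4 in skin and 1 (Gm9385) for monocyte against blood, and only blood names in the same place in both orders gave 2 (Gm15501 and Gm9385). Leaving out each library in turn gave 0 in blood, neutrophil, monocyte and skin and for neutrophil against blood, 0 to 8 for monocyte against blood and 0 to 11 for neutrophil against monocyte. The 8 and the 11 both arose without the library labelled Monocyte_IVIG replicate 3.

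Of the gene lists called with the preset correlation (5, 6, 6 and 14 in blood, neutrophil, monocyte and skin, 10, 10 and 9 in Ics, and 8, 3 and 3 for the differences), an estimated correlation left 0, except 1 for neutrophil against blood, the interferon list. Without each library in turn, the preset correlation called 6 to 11 lists in blood, 2 to 17 in neutrophil, 4 to 9 in monocyte and 6 to 20 in skin, and with only libraries whose markers match their label 13, 6, 4 and 14, of which 3, 4, 3 and 12 were among those called with all libraries. The 11 arose without Blood_IVIG replicate 2 or Blood_PBS replicate 1, the 2 without Neutrophil_IVIG replicate 1, the 17 without Neutrophil_IVIG replicate 5, which had blood markers, and the 6 in skin without Skin_IVIG replicate 2, and the cause was not tested. The estimated correlation called 0 in each of these. For neutrophil against blood, the preset correlation called 6 to 16 lists without each library in turn and 13 with only libraries whose markers match their label, and the 16 arose without Blood_PBS replicate 2. The interferon list stayed called with an estimated correlation in 10 of the 28 leave-out fits, and its adjusted p was 0.655 without Blood_IVIG replicate 3, which had skin markers, and 0.9 with only libraries whose markers match their label. Fry called 0 in the IVIG comparisons and the differences, and 23, 25 and 23 in Ics. The Ics response sets went from 2 called to 0 with an estimated correlation and to 4 when taken from 6 h, whose adjusted p with an estimated correlation was 0.624 to 0.86.

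The following values changed sign, none past the threshold, and the cause was not tested unless given. In blood, Fcgr2b was -0.0893 by limma voom and -0.37 with only names in the same place, and S100a9, at -4.46 with all libraries, ran from -5.09 to 0.20 without each library in turn, the latter without Blood_PBS replicate 1, which had neutrophil markers. In neutrophil, Fcgr2b was -0.11 in title series 3 alone and ran from -0.10 to 0.19 without each library, the former without Neutrophil_PBS replicate 1. In Ics at 3 h, Fcgr4 ran from -0.0630 to 0.0149 and S100a8 from -0.124 to 0.0401 without each library. The depth was 18965434 to 43176793 counts per library, and genes under the filter's minimum count of 10 were not tested.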

Other observations

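The test of Nrf2 targets was chosen after the result was seen. Members of other lists fixed in advance rose or fell in the Ics experiment. Of 16 monocyte and macrophage genes, 8 rose and 8 fell at 3 h, with 8 and 8 adjusted over the list alone (camera adjusted p = 0.408). The endotoxin receptor gene Cd14 rose by 3.86 ± 0.121 (SE, n = 4 and 4 libraries), from 87.6 ± 9.54 to 1272 ± 111 CPM, Adgre1 by 2.55 ± 0.0798 and the growth factor receptor gene Csf1r by 1.65 ± 0.0813. Ly6c2, named after its value was seen, was at -0.48 ± 0.0637. Of 9 genes of MHC class II presentation, 6 rose and 3 fell at 3 h, with 6 and 3 adjusted over the list alone (camera adjusted p = 0.376), and between 3 h and 6 h 0 rose and 4 fell, with 0 and 4 adjusted over the list alone (camera adjusted p = 0.0498, and adjusted p = 0.626 with an estimated correlation). H2-Eb1 rose by 3.30 ± 0.195 at 3 h and was at -2.42 ± 0.184 from there to 6 h.

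Of 13 transcripts of the mitochondrial genome, 9 fell and 0 rose at 3 h, with 9 and 0 adjusted over the list alone (camera adjusted p = 0.0442, and adjusted p = 0.79 with an estimated correlation). At 6 h 11 fell and 0 rose, with 11 and 0 adjusted over the list alone (camera adjusted p = 0.00125, and adjusted p = 0.614 with an estimated correlation). Of 7 leukotriene genes, 5 fell and 0 rose between 3 h and 6 h, with 5 and 0 adjusted over the list alone (camera adjusted p = 0.0498, and adjusted p = 0.626 with an estimated correlation). Of 6 tested adipocyte genes, 6 fell and 0 rose at 6 h, with 6 and 0 adjusted over the list alone (camera adjusted p = 0.0202, and adjusted p = 0.472 with an estimated correlation). The superoxide dismutase gene Sod2 rose by 4.81 ± 0.139 at 3 h, from 20.4 ± 1.87 to 575 ± 85.5 CPM. The receptor gene Trem1 was at -1.81 ± 0.0625 at 6 h, and the decoy receptor gene Il1r2 at -3.08 ± 0.0975.

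The rise of Nqo1, Srxn1 and Prdx1 prompted the hypothesis that targets of the transcription factor Nrf2 may respond as a group. The list held 23 targets, of which 21 were tested at 6 h against 0 h. The genes first seen, which were more than those named here, were then left out. The 14 targets that remained had 13 rise and 1 fall, with a median of 2.22 and a camera p of 9.63e-09. The estimated correlation between them was 0.645, and with it the p was 0.0775, so the test leaves open whether the group differs from other genes. At 3 h 11 rose and 2 fell, with a median of 1.19. Between 3 h and 6 h 9 rose and 0 fell, with a median of 0.525.

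In the 8 libraries of the class that holds most libraries labelled monocyte, the mitochondrial transcript mt-Co1 held 1.30 to 29.4% of the counts, against 0.128 to 0.225% in the Ics libraries. It held 1.33 to 2.29% in the skin class, 0.102 to 0.832% in the neutrophil class and 0.0191 to 0.231% in the blood class. Most of the 8 enter the monocyte comparison.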
